A study of Mus musculus with 8 samples.

How the data were processed

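The data were 1 table of ATAC-seq counts over a region set shared by 8 libraries of sorted splenic cDC1, 4 WT and 4 OPA1-deficient. Per the labels, cells were lysed and nuclei were treated with transposase before the DNA was purified and amplified. Per the submitters' processing notes, cutadapt 1.9, Picard 1.65, SAMtools, MACS2 2.1.0.20150603 and bedtools were used with the mouse builds mm10 and GRCm38. The role, order and settings of these tools, any shift of read ends for the transposase, any blacklist, and the rule that made the common region set were not given in the sources used here. The deposited values are counts: whole numbers whose totals differ between libraries, with no normalization. Even counts made up 54.1% to 59.9% of values per library, and 23 of the 24 counts at the 3 regions of chromosome Y were even. Whether both ends of read pairs were counted was left open, and the values were used as deposited. Whether starts count from 0 or 1 was not given, and coordinates are printed as in the table. Each column was assigned to its library through the library name in the labels.

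The table held 59839 regions on placed chromosomes and 67 on unplaced scaffolds, with no overlapping neighbours. Total counts ranged from 4660826 to 7590578 per library, and the median count per region and library was 42. No libraries were duplicates: over the 12 pairs within groups, the chi-square of their counts per degree of freedom was 2.16 to 4.74, and log2 CPM correlated across regions at 0.930 to 0.955 within groups and 0.922 to 0.950 between them. Regions are not independent replicates.

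Regions were filtered with filterByExpr, which left 59247 and removed 659, and scaled with TMM factors (0.947 to 1.03). Differences were tested with edgeR 4.0.16 in R 4.3.3, using estimateDisp, glmQLFit with robust estimation and the default quasi-likelihood method of that version, and glmQLFTest, over all 8 libraries without covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested regions, with calls at 0.05. The common dispersion was 0.0270, a biological coefficient of variation of 0.164. Standard errors came from the same model. Comparisons of single values between groups used two-sided exact permutation tests over the 70 assignments of 4 against 4, which cannot give a p below 0.0286. All p-values cover these 8 libraries alone.

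Genes were taken from a table of RefSeq gene models on GRCm38, of which the 21887 protein-coding models were used. It gives gene spans without strand, exons or introns. The planned promoter definition was therefore replaced by a region within 1 kb of either end of a model, called a gene end. Of 11997 models with a tested region at an end, 10494 (87.5%) had regions at 1 end only. Other regions were classed as inside a gene or between genes, and a called region was assigned to the nearest gene within 50 kb. Exon and intron positions, which need an annotation with exons, and motifs and GC content, which need a genome sequence, were not analysed here.

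The 30 gene lists held 945 genes, of which 944 matched a gene model and 800 had a tested region at an end. Each gene was represented by the region with the highest mean CPM among those at its ends, and genes sharing a region were counted as 1. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated per list. The groups, lists, tests, most alternatives and the rule for naming genes were fixed before the data were examined. That rule named the regions of Opa1 and the Itgax gene end; called regions with separated groups, a mean CPM at or above the median and a gene within 50 kb, up to 12 in each direction by log2 fold change with 1 region per gene; up to 4 called members per list, or up to 2 with the smallest p where none was called; and all called regions of a direction with fewer than 5. Macrophage genes with values near 0, and called regions outside the rule, were named after their values were seen. A gene that the rule named is not reported here.

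The procedure was tested on simulated data for this comparison, drawn with the means, dispersions and library sizes of the real libraries, with 200 of 59011 regions changed. It recovered 16 of 67 regions changed by 1.5-fold (23.9%), 29 of 67 changed by 2-fold (43.3%) and 56 of 66 changed by 3-fold (84.8%), each in the right direction, and called 4 unchanged regions. With no region changed it called 0. A list moved by 1.3-fold was called, and 0 of the other lists. Regions were drawn independently of one another, without structure among the libraries. Splits of the real libraries that mix the groups called up to 1417 regions and up to 9 lists. The simulated rates of false calls therefore need not hold for the real data.

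The alternatives were DESeq2 size factors, total counts or loess offsets in place of TMM factors, DESeq2 1.42.0 or limma-voom in place of edgeR, no filter or a stricter one (CPM of at least 2 in 4 libraries), other thresholds, sex chromosomes left out, other distances for gene ends and windows, a block for the replicate number, and each library left out in turn. Some fits were added after the data were seen and are identified as such with their effects. Among them is the newer quasi-likelihood method of the same edgeR version, which was run before the default was settled on as the one the fixed design implied.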

Results

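Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in conventional type 1 dendritic cells (cDC1) sorted from mouse spleen. These dendritic cells specialise in presenting captured antigen to CD8 T cells. The 8 libraries comprised 4 from WT mice and 4 from mice in which the CD11c-Cre recombinase acted on a floxed Opa1 gene. OPA1 is a GTPase of the inner mitochondrial membrane that fuses mitochondria and shapes their cristae. The table held counts over 59906 regions with a median width of 323 bp. Counts in regions totalled 6426149, 6777651, 4660826 and 5649829 in WT replicates 1 to 4, and 6906283, 5522153, 7590578 and 5929281 in OPA1-deficient replicates 1 to 4. Levels are given as TMM-scaled CPM, the share of a library's counts scaled to a common depth,, as mean ± SD with n = 4 per group, and log2 fold changes are OPA1-deficient minus WT ± standard error. The labels do not tie each library to an animal, so the p-values measure the spread between these libraries, which may be technical.

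The comparison asked how loss of OPA1 in CD11c-expressing cells affected chromatin accessibility in splenic cDC1. At the targeted gene, Opa1 (chromosome 16, 29579281 to 29663127, GRCm38), 1 region was tested, over an end of the gene model at 29579132 to 29579622. Its level was 42.1 ± 3.86 CPM in WT and 39.2 ± 3.73 CPM in OPA1-deficient cells (n = 4 each, log2 fold change −0.11 ± 0.12, edgeR quasi-likelihood adjusted p = 0.924). In single libraries the level was 47.0, 40.7, 42.9 and 37.9 CPM in WT and 34.6, 41.4, 38.0 and 43.0 CPM in OPA1-deficient cells. The labels do not give the deleted part of the gene, so this value does not check the genotype.

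Regions at Itgax, which encodes the integrin CD11c and whose regulatory sequence drives the Cre transgene, rose in OPA1-deficient cDC1 and were the 3 regions called higher. Inside the gene, the region at 128133563 to 128134068 on chromosome 7 rose from 41.3 ± 6.13 to 97.1 ± 13.7 CPM (log2 fold change 1.23 ± 0.11, edgeR adjusted p = 1.84e-07), and the region at 128138346 to 128138777 rose from 31.6 ± 7.44 to 63.1 ± 11.5 CPM (1.00 ± 0.16, edgeR adjusted p = 0.0279). The region at 128128823 to 128129098, 428 bp outside the Itgax model, rose from 7.31 ± 0.831 to 15.2 ± 1.34 CPM (1.06 ± 0.19, edgeR adjusted p = 0.0290). In all 3 regions, the 4 OPA1-deficient libraries lay above the 4 WT libraries. The region over the end of the Itgax model, at 128129222 to 128129684, was at 22.3 ± 4.63 CPM in WT and 30.8 ± 3.49 CPM in OPA1-deficient cells and did not pass the test (0.47 ± 0.15, edgeR adjusted p = 0.503).

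The higher values at Itgax were part of a stretch that held neighbouring integrin genes. Within 150 kb of Itgax, 3 of 30 tested regions were called (10%), against 9 of 59217 elsewhere (0.0152%, two-sided Fisher's exact p = 2.57e-08, with regions that are not independent of one another). A run of 17 consecutive regions from 128063285 to 128210087 had positive log2 fold changes, from 0.22 to 1.63 with a median of 1.00. The run spanned Itgam, which encodes CD11b, Itgax and Itgad, which encodes CD11d, and ended near Cox6a2, a muscle-type subunit of cytochrome c oxidase. Counts summed over the run were 191 ± 24.2 CPM in WT and 359 ± 41.5 CPM in OPA1-deficient cells, a ratio of 1.88. Over the other 44 regions within 500 kb, the sums were 1168 ± 51.7 and 1170 ± 38.7 CPM. The run was delimited by the sign of its values after they were seen, so a test of either sum would be void and none is used here. The labels do not say which CD11c-Cre transgene was used or whether the WT mice carried Cre, and no DNA input was analysed here, so counts here were not corrected for DNA copy number. Of the 3 called regions, that at 128133563 was called in each of the 8 fits that left out 1 library (largest edgeR adjusted p = 1.46e-05). The count within 150 kb was 7 without WT replicate 2, 5 without OPA1-deficient replicate 4, and 1 without WT replicate 3 or 4 or OPA1-deficient replicate 1, 2 or 3.

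**Figure D1:**
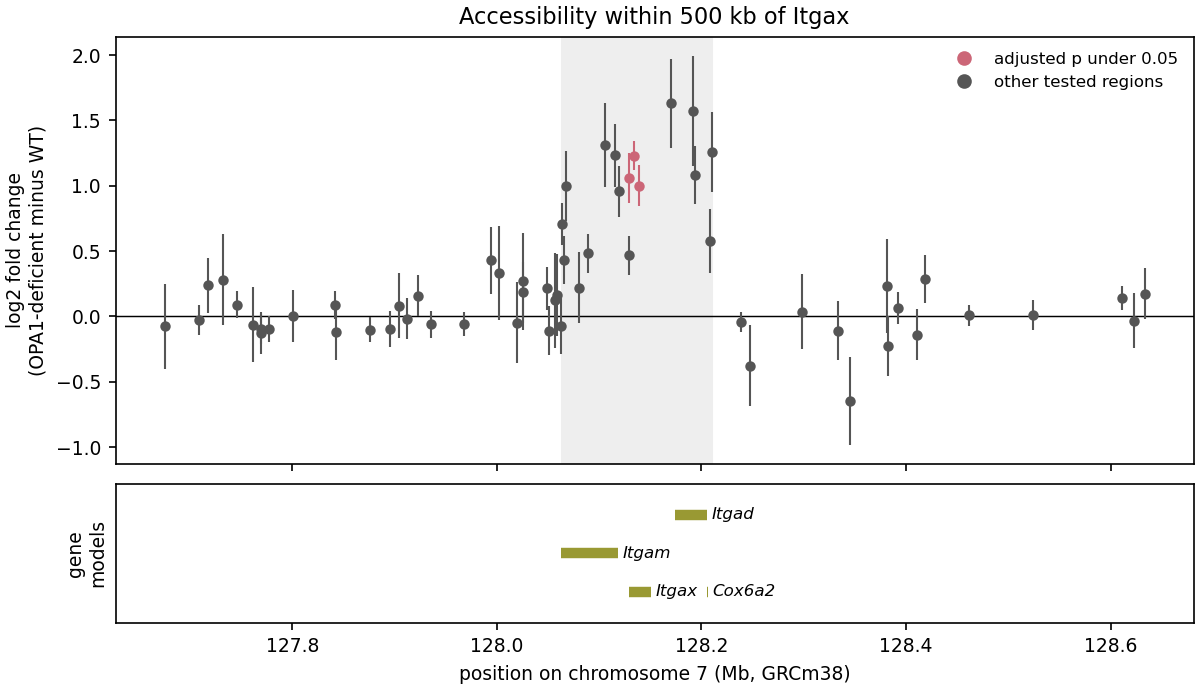
Log2 fold change (OPA1-deficient minus WT, bars showing the standard error) of the 61 tested regions within 500 kb of Itgax against position on chromosome 7 in Mb, with the gene models beneath; shading marks the run of 17 consecutive positive values. The 3 called regions are coloured, and the regions next to the shaded run lie at −0.07 and −0.04.

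Accessibility fell at 9 regions outside this neighbourhood. A region 5.91 kb from Clca2, which encodes a regulator of chloride conductance, fell from 19.04 ± 3.82 to 7.67 ± 1.94 CPM (chromosome 3, 145105355 to 145105966, log2 fold change −1.32 ± 0.20, edgeR adjusted p = 0.00882). Inside Enpp2, which encodes autotaxin, the enzyme that makes lysophosphatidic acid, a region fell from 15.6 ± 3.66 to 7.0 ± 1.42 CPM (chromosome 15, 54929271 to 54929842; −1.15 ± 0.21, edgeR adjusted p = 0.0371). A region inside Gramd1b, which encodes a cholesterol transfer protein of the endoplasmic reticulum, fell from 30.2 ± 5.0 to 17.1 ± 2.23 CPM (chromosome 9, 40321128 to 40321838; −0.81 ± 0.15, edgeR adjusted p = 0.0418).

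The other 6 lower regions were less abundant or had no gene within 50 kb, and are named here after their values were seen. They included a region inside Rars2, the mitochondrial arginyl-tRNA synthetase gene, which fell from 9.61 ± 2.89 to 2.97 ± 1.01 CPM (chromosome 4, 34642912 to 34643552, log2 fold change −1.69 ± 0.28, edgeR adjusted p = 0.0154). Regions 1.70 kb from Cdk5rap2, a centrosomal protein gene, and 28.4 kb from Gspt1, a translation termination factor gene, fell with log2 fold changes of −1.71 ± 0.30 and −1.67 ± 0.29 (chromosome 4, 70412135 to 70412335, and chromosome 16, 11282764 to 11283168, edgeR adjusted p = 0.0276 for both). The 3 without a gene nearby were at 52396338 to 52396720 on chromosome 12 (−1.66 ± 0.27), 15066341 to 15066885 on chromosome 14 (−1.48 ± 0.26) and 17597006 to 17597627 on chromosome 15 (−1.32 ± 0.25), with edgeR adjusted p of 0.0106, 0.0290 and 0.0418. At 8 of the 9 regions each OPA1-deficient library lay below each WT library; the exception was the region on chromosome 14, where WT replicate 2 was at 6.86 CPM, under the highest OPA1-deficient value of 6.89 CPM. Marker regions of monocytes and macrophages were lower as a list in the same libraries (median log2 fold change −0.14, camera adjusted p = 0.0402), a call lost with an estimated correlation (adjusted p = 0.833). Regions called lower by edgeR numbered 54 without WT replicate 2, 16 without OPA1-deficient replicate 4, 5 without WT replicate 1, 3 without OPA1-deficient replicate 2, and 0 without WT replicate 3 or 4 or OPA1-deficient replicate 1 or 3, where 3204 to 3539 regions in both directions had an unadjusted p under 0.05.

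**Figure D2:**
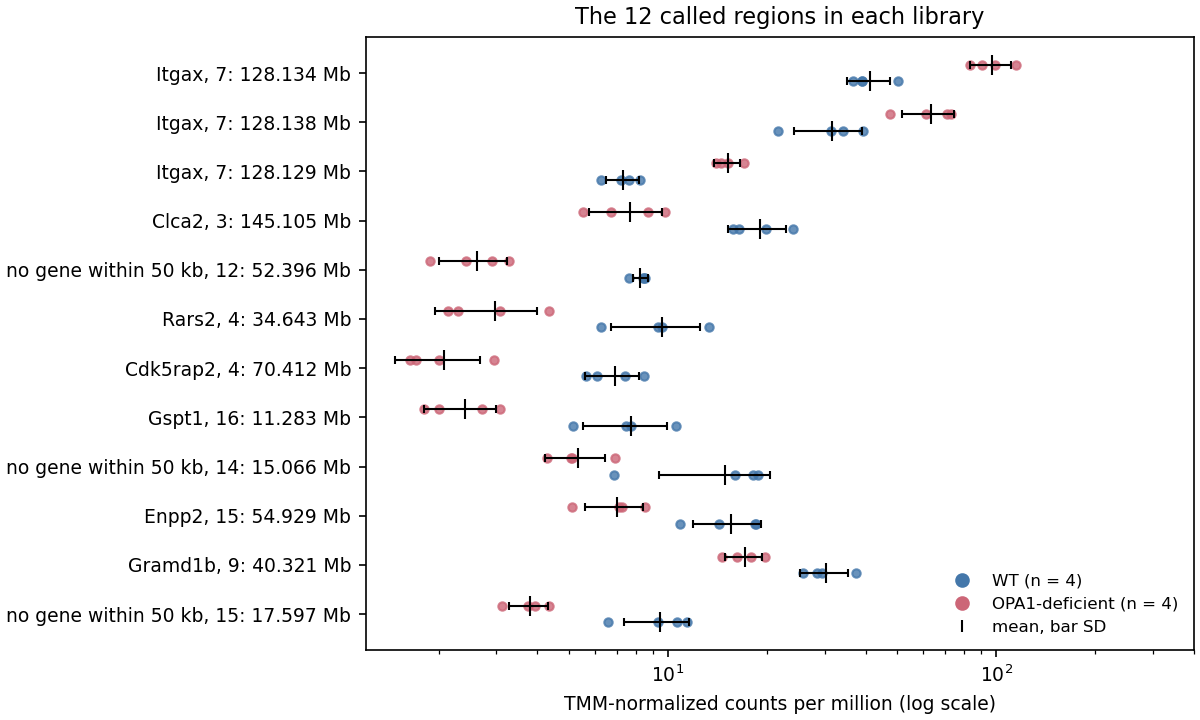
TMM-normalized CPM (log axis) of the 12 called regions in each library, with 4 WT and 4 OPA1-deficient points per region and the mean with SD bars in black; labels give the nearest gene within 50 kb, chromosome and start. The groups do not overlap except at the region on chromosome 14.

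In all, 12 of 59247 tested regions passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 higher and 9 lower. By class, the 12 were 1 of 13254 regions at gene ends, 5 of 25130 inside genes and 6 of 20798 between genes. At an unadjusted p under 0.05 there were 3782 regions, 1730 higher and 2052 lower, where chance alone gives 2962 on average. Other splits of the 8 libraries into 4 and 4, which mix the groups, gave 1302 to 9023 such regions. The excess over 2962 is therefore not by itself a sign of genotype. Of the 3782, 141 were higher and 426 lower at gene ends, 871 and 890 inside genes, and 716 and 736 between genes. The groups did not overlap in 3.95% of regions, against 2.86% by chance. DESeq2 called 43 regions and limma-voom 4. The count was 68 without WT replicate 2, 22 without OPA1-deficient replicate 4, 4 without OPA1-deficient replicate 2, and 1 without WT replicate 3 or 4 or OPA1-deficient replicate 1 or 3.

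Regions at the ends of genes for mitochondrial functions gave log2 fold changes close to 0, and no such list passed camera's test. Lower values were found for 25 of 35 regions of respiratory complex I genes, which oxidise NADH (median log2 fold change −0.03, adjusted p = 0.495), for 25 of 35 of genes for complexes II to V (−0.04, adjusted p = 0.495) and for 46 of 72 of mitochondrial ribosome genes (−0.04, adjusted p = 0.495). The same held for 19 of 29 regions of genes for mitochondrial dynamics and cristae (−0.05, adjusted p = 0.495), 18 of 29 for mitochondrial DNA maintenance and biogenesis (−0.03, adjusted p = 0.639), and 23 of 34 for the tricarboxylic acid cycle and fatty acid oxidation (−0.05, adjusted p = 0.495). Members with the smallest p included Ndufa9 of complex I (−0.32 ± 0.17), Uqcrb of complex III (−0.29 ± 0.12), Cox6b1 of complex IV (−0.33 ± 0.15), Idh3b of isocitrate dehydrogenase (−0.41 ± 0.18), the mitochondrial fission factor Mff (−0.24 ± 0.11), and Mrpl46 and Mrps11, which share 1 region (−0.31 ± 0.13). None of these regions passed the test over all regions or adjusted over the list alone. Without WT replicate 2, 16 of 35 regions for complexes II to V (median 0.01) and 14 of 29 for dynamics and cristae (0.00) were lower, and without OPA1-deficient replicate 1, 13 of 29 for mitochondrial DNA maintenance and biogenesis (0.02). The median over all tested regions at gene ends was −0.03, so these medians were near that of the class. All lists hold regions at gene ends, while camera set each list against tested regions of every class. Of the 30 lists, 21 had a median under 0. A majority of lower regions, here or in the lists below, is therefore not by itself particular to a list.

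Genes of the integrated stress response, the ATF4 programme that mitochondrial dysfunction can induce, had 20 of 33 regions higher (median log2 fold change 0.01, camera adjusted p = 0.581). Among them Chac1, a glutathione-degrading enzyme gene, was at 0.49 ± 0.17 and Psat1, a serine synthesis gene, at 0.33 ± 0.14, and neither passed the test. Of the NRF2 antioxidant genes, 15 of 22 regions were lower (−0.03, adjusted p = 0.495), with Hmox1 at −0.32 ± 0.14 and Keap1 at −0.19 ± 0.13. Autophagy and lysosome genes had 43 of 65 regions lower (−0.03, adjusted p = 0.495), with the lysosomal membrane gene Lamp2 at −0.37 ± 0.14. Glycolysis genes had 12 higher and 11 lower (0.00, adjusted p = 0.786), cell cycle genes 17 and 19 (−0.01, adjusted p = 0.825), and apoptosis and p53 genes 11 and 13 (0.00, adjusted p = 0.936). The cyclin genes Ccnb1 and Ccnd2 were at 0.36 ± 0.12 and −0.45 ± 0.21. Leaving out 1 library turned the median for autophagy and lysosome genes (0.00 with 30 of 65 lower, without WT replicate 2) and for the integrated stress response (−0.01 with 14 of 33 higher, without OPA1-deficient replicate 3). It also turned the medians for glycolysis (without WT replicate 1 or 4 or OPA1-deficient replicate 1, 2 or 3, −0.03 to −0.01), cell cycle (without WT replicate 1, 2 or 4, 0.00 to 0.01) and apoptosis (without WT replicate 2 or 4 or OPA1-deficient replicate 3 or 4, 0.01 to 0.03).

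Genes of dendritic cell function showed no list that passed the test. Regions of MHC class I presentation genes were lower in 16 of 26 (median log2 fold change −0.01, camera adjusted p = 0.639) and those of MHC class II presentation in 11 of 15 (−0.02, adjusted p = 0.740). Costimulation and maturation genes had 15 of 25 regions lower (−0.05, adjusted p = 0.521). In this list the T cell ligand gene Cd70 was at 1.34 ± 0.45 and Eno3, an enolase gene, at −0.57 ± 0.20. Levels at Cd70 were low, 1.08 CPM in WT and 2.82 CPM in OPA1-deficient libraries. Cytokine and chemokine genes had 14 higher and 11 lower (0.01, adjusted p = 0.731), with Il10 at 0.37 ± 0.16 and Cxcl10 at −0.29 ± 0.13. Type I interferon genes were lower in 24 of 37 regions (−0.04, adjusted p = 0.740), AP-1 and immediate early genes in 21 of 28 (−0.03, adjusted p = 0.521), dendritic cell transcription factors in 23 of 37 (−0.05, adjusted p = 0.521) and chromatin regulators in 23 of 35 (−0.01, adjusted p = 0.521). Among the transcription factors, Runx3 was at 0.48 ± 0.17 and Ikzf2 at −0.35 ± 0.13. Targets of NF-κB were lower in 17 of 24 regions (−0.06, adjusted p = 0.495). Of these, Bcl2a1a, an anti-apoptotic BCL2 family gene, passed adjusted over the list alone (−0.74 ± 0.22, edgeR adjusted p = 0.0472) and not over all regions; near-identical gene copies make its counts uncertain. Without WT replicate 1, the lists of NF-κB targets and of AP-1 genes passed camera's test, both lower (adjusted p = 0.00793 and 0.0476), and both calls were lost with an estimated correlation (adjusted p = 0.678 for each). Without WT replicate 2 the direction of both medians turned (0.02 and 0.03), with 10 of 24 and 10 of 28 regions lower, as did those for MHC class I (0.03, 11 of 26 lower) and costimulation genes (0.02, 11 of 25 lower). The MHC class I median also turned without WT replicate 4 or OPA1-deficient replicate 4 (0.02 for both), and that of cytokine and chemokine genes without WT replicate 1 or 3 or OPA1-deficient replicate 1, 2 or 3 (−0.05 to −0.02).

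Among the markers of cell types, regions of monocyte and macrophage genes fell as a list in OPA1-deficient libraries, with 18 of 25 lower and a median log2 fold change of −0.14 (camera adjusted p = 0.0402 with a preset correlation of 0.01). The adjusted p was 0.833 with an estimated correlation, so the call was lost. That value was shared by most lists, and the unadjusted camera p of this list was 0.0575. C1qb, a complement component gene, was at 7.68 CPM in WT and 4.20 CPM in OPA1-deficient libraries (−0.87 ± 0.26), with all 4 OPA1-deficient libraries below the WT mean. It was among the 2 members that passed adjusted over the list alone (edgeR adjusted p = 0.0234), and 0 passed over all regions. The scavenger receptor gene Cd68 (0.00 ± 0.10) and the receptor genes Csf1r (−0.04 ± 0.17) and Adgre1 (0.20 ± 0.23) had values near or above 0. The median was −0.06 without WT replicate 2 or OPA1-deficient replicate 4, −0.09 without WT replicate 4 and −0.21 without WT replicate 1. The list was also not called without WT replicate 2, 3 or 4 (adjusted p = 0.317, 0.115 and 0.454) or OPA1-deficient replicate 1, 3 or 4 (adjusted p = 0.0560, 0.0588 and 0.453), with loess offsets (adjusted p = 0.0773), or over all regions nearest each gene within 50 kb (adjusted p = 0.210).

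Markers of cDC1 themselves had 16 of 27 regions higher (median log2 fold change 0.06, camera adjusted p = 0.521). The member with the smallest p was the region over the end of Itgax (0.47 ± 0.15), which lay in the run around Itgax. Markers of cDC2, the other conventional dendritic cell subset, were lower in 16 of 21 regions (−0.11, adjusted p = 0.648). In this list the Itgam region at 128063285 passed adjusted over the list alone (0.71 ± 0.16, edgeR adjusted p = 0.00289) and lay in the run around Itgax. Plasmacytoid dendritic cell markers had 7 of 13 regions higher (0.01, adjusted p = 0.639), B cell markers 4 of 13 (−0.03, adjusted p = 0.883), T cell markers 7 of 10 (0.12, adjusted p = 0.581), NK cell markers 5 of 7 (0.16, adjusted p = 0.825), neutrophil markers 7 of 14 (0.01, adjusted p = 0.581) and red cell markers 9 of 12 (0.14, adjusted p = 0.495). Examples were the plasmacytoid marker Fcrla (0.63 ± 0.25), the T cell factor gene Tcf7 (0.47 ± 0.24), the perforin gene Prf1 (−0.95 ± 0.35) and the red cell membrane gene Epb42 (1.01 ± 0.48), none of which passed the test. Levels were low at Prf1 (4.36 CPM in WT, 2.25 CPM in OPA1-deficient) and Epb42 (1.59 ± 0.847 and 3.31 ± 2.33 CPM). At Epb42, 2 OPA1-deficient libraries lay above the WT mean and 2 below. Leaving out 1 library turned the medians of plasmacytoid markers (without WT replicate 2 or 3 or OPA1-deficient replicate 2, 3 or 4, −0.05 to 0.00), B cell markers (without WT replicate 1 or 3 or OPA1-deficient replicate 1, 2 or 3, 0.00 to 0.04) and neutrophil markers (without WT replicate 1 or OPA1-deficient replicate 1 or 3, −0.06 to 0.00). Over the 790 regions of the 30 lists, edgeR called 0, DESeq2 0 and limma-voom 0 after adjustment over all regions, and 36 had an unadjusted p under 0.05 in edgeR. Median, mean and test differed in sign for glycolysis, cytokine and chemokine, cell cycle, apoptosis and B cell lists.

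**Figure D3:**
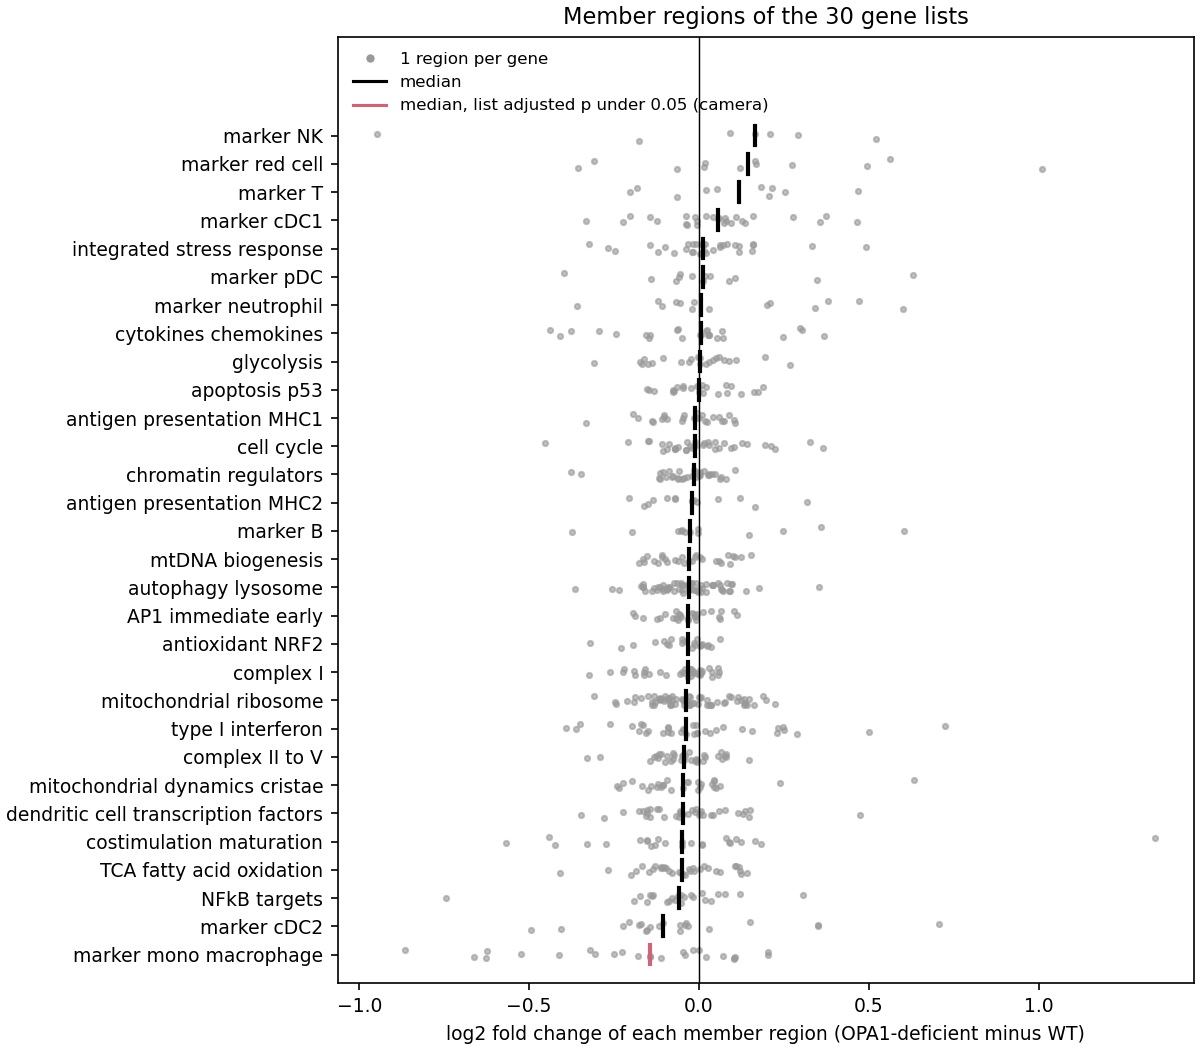
Log2 fold change (OPA1-deficient minus WT) of the regions of the 30 gene lists, 1 point per region, with the median of each list as a vertical bar. The monocyte and macrophage list, with its bar coloured at −0.14, was the list called with the preset correlation.

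Regions at gene ends took 52.6% ± 0.322 of the counts in WT and 52.1% ± 0.577 in OPA1-deficient libraries (n = 4 each), a difference of −0.556 percentage points that did not pass the test (two-sided exact permutation p = 0.171) and was −0.272 without OPA1-deficient replicate 1. The median log2 fold change was 0.10 in the least abundant and −0.03 in the most abundant of 10 equal bins of regions. The first principal component of log2 CPM held 21.9% of the variance and did not separate the groups (exact permutation p = 0.657). The second held 18.5% and separated them (exact permutation p = 0.0286, the smallest possible, with 7 components tested).

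**Figure D4:**
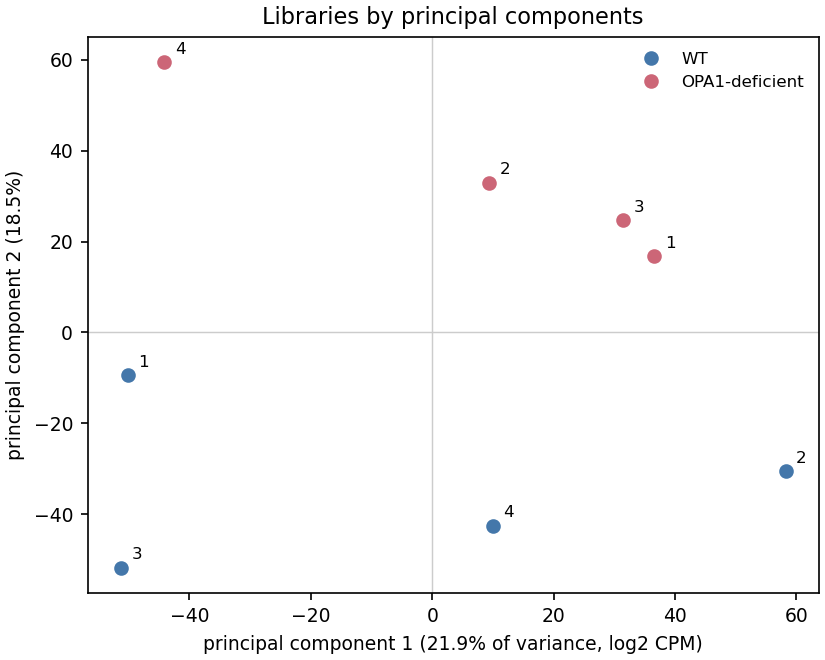
The 8 libraries on the first and second principal components of log2 CPM, which hold 21.9% and 18.5% of the variance; numbers are replicate numbers. The 4 OPA1-deficient libraries lie above 0 on the second component and the 4 WT libraries below, while both groups spread along the first.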

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

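The tests of extra DNA copies, of opening of Itgax alone, of other splits for the Itgax regions and of the abundance trend were chosen after the results they concern were seen.

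Single libraries far from the other 3 of their group were sought in 170 groups of values with Dixon's criterion at the 95% level, and 8 were found, where chance gives about 1 in 20. OPA1-deficient replicate 1 had 20.8% of its counts between genes, against 20.3% in each of the other 3. At the region called lower on chromosome 12, at 52396338, WT replicate 3 was at 7.60 CPM and the others at 8.42 to 8.52. The Dnmt3b region was at 13.1 CPM in WT replicate 3 and 16.7 to 16.9 in the others. The Eno3 region was at 14.0 CPM in WT replicate 4 and 10.1 to 10.4 in the others, and the Ankrd37 region was at 108 CPM in WT replicate 1 and 124 to 126 in the others. Among OPA1-deficient libraries, the region over the end of Itgax was at 25.6 CPM in replicate 4 and 32.3 to 33.0 in the others. The Tcf7 region was at 7.80 CPM in OPA1-deficient replicate 2 and 6.55 to 6.57 in the others, and the Slc25a46 region at 41.5 CPM in replicate 4 and 36.0 to 36.2 in the others.

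For the first pattern, the stretch of higher counts around Itgax, opening of Itgax alone is argued against, since the 8 regions within 50 kb but over 1 kb from its gene model had a median log2 fold change of 1.16, with summed counts of 48.2 ± 5.43 CPM in WT and 87.3 ± 7.16 CPM in OPA1-deficient libraries, a pattern already seen when this set was drawn. Extra DNA copies of this stretch in the OPA1-deficient cells, as a Cre transgene carrying Itgax sequence could bring, remain a candidate explanation. The 12 regions within 50 kb had a median of 1.07, but all lie in the run already seen to be positive. The median was 0.45 over the 30 regions within 150 kb (25 higher, 5 lower). It was −0.02 over the 31 regions at 150 to 500 kb (14 higher, 17 lower). The window distances were set without regard to sign, and wider regulation could also give these values. The call of the region at 128133563 did not rest on 1 library. Its edgeR adjusted p was 1.84e-07, at most 1.46e-05 in each of the 8 fits that left out 1 library, and 1.21e-05 with limma-voom. These fits keep the same grouping, and the smallest p of other splits was not kept. Chance was therefore not tested for this region. As many as 3 regions within 150 kb were called in 2 of 35 splits, the real one and 1 other, and the remaining splits called none there. The other split called 4, with WT replicates 1, 3 and 4 still together, joined by OPA1-deficient replicate 4. It kept much of the genotype contrast and called 1203 regions in all, so its cutoff was looser. The count of 3 therefore neither excludes chance nor speaks for it. Wider regulation of the integrin cluster stays open and untested, since no DNA input was analysed here and the labels give neither the transgene used nor whether the WT mice carried Cre.

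The second pattern is the number of calls, among which the region at 128133563 had the smallest edgeR adjusted p (1.84e-07). For the count of 12 chance could not be excluded, as 4 of 35 splits called as many regions, with 1417 in the highest other, and for the 9 calls over 500 kb from Itgax 4 of 35 splits called as many, with 1416 in the highest other. The 3 other splits called 1417, 1203 and 72 regions, each with WT replicates 1 and 3 and OPA1-deficient replicate 4 on one side, which points to a structure among the libraries that does not follow genotype. A fit with the first principal component of the residuals as a covariate, added after the data were seen, called 156 regions and included all 12. That component was drawn from these same residuals, so a smaller spread was built in. The rise in calls therefore cannot show what this structure does to the comparison. No biological explanation of the 9 lower regions was tested.

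For the third pattern, the lower value of monocyte and macrophage marker regions, chance could not be excluded. Of 35 splits, 17 called as many lists of any kind, with 1 in the real split and 9 in the highest other. Whether the macrophage list was called in other splits was not kept, so this count does not test that list itself. Fewer macrophages in the OPA1-deficient sorts is a possible explanation that these values could not decide: after removal of group means, the list and the 9 lower regions correlated across the 8 libraries with Pearson r = 0.0874 (permutation p = 0.840) and Spearman rho = 0.405 (permutation p = 0.403), and r was 0.586 without the 2 farthest libraries. The most abundant members, Axl (136 ± 6.88 CPM in WT, 138 ± 9.22 CPM in OPA1-deficient) and Cd68 (95.4 ± 11.4 and 95.4 ± 12.5 CPM), differed by less than the spread between libraries. If these regions are open in the cDC1 themselves, a small admixture would hardly change them, so they do not decide this either. Of the 25 genes, 5 are also in another list, and a sort for cDC1 is meant to remove macrophages. By the list median, the measure set for this test, the trend of fold change with abundance could not be decided (−0.11 under loess offsets, −0.14 without them). The list mean was −0.19 with and without loess offsets, and the lowest median of the 10 bins by abundance was −0.03. These values argue against the trend as the source of most of the decrease. An effect of OPA1 loss on the cDC1 themselves stays open and untested.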

How the results depend on the processing

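The fits with the newer quasi-likelihood method, without 500 kb around Itgax, without unplaced scaffolds and with a residual component, and the replicate block for the Itgax regions, were chosen after the results were seen. The 12 called regions kept their direction in every alternative that tested them. DESeq2 size factors, no filter, the stricter filter, a log2 fold change of at least 0.5, no sex chromosomes and no scaffolds each called the same 12. Loess offsets called 12, of which 11 were shared, total counts called 9, all shared, and the newer method called 17, 4 higher and 13 lower, with all 12 among them. DESeq2 called 43 regions (10 higher, 33 lower, 3446 adjusted p not given), limma-voom 4 (2 higher, 2 lower), and an adjusted p under 0.01 left 2 (1 and 1). Without 500 kb around Itgax there were 6 (0 higher, 6 lower; 3765 at an unadjusted p under 0.05), as a set with fewer small p-values was adjusted. With the residual component there were 156 (39 higher, 117 lower). For the other changes the cause was not tested.

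Leaving out each library gave 1 to 68 calls, 1 to 14 higher and 0 to 54 lower: 68 without WT replicate 2, 22 without OPA1-deficient replicate 4, 8 without WT replicate 1, 4 without OPA1-deficient replicate 2 and 1 without any of the others. The 12 named regions gave 1 to 12, and limma-voom called 4 of them. Regions within 150 kb of Itgax gave 1 to 7, and 3 with the other windows, total counts and loess offsets. The Opa1 region stayed at −0.15 to −0.04, and the difference in gene-end share at −0.690 to −0.272 percentage points, the latter without OPA1-deficient replicate 1 (−0.525 at 500 bp, −0.559 at 2 kb). Called gene lists numbered 0 to 3 (3 without WT replicate 1, 1 without OPA1-deficient replicate 2, 0 without any of the others), 0 with an estimated correlation, 0 over regions nearest each gene, 0 with loess offsets and 1 with total counts; the macrophage list's adjusted p ranged from 0.00197 to 0.833. Of the results for single named regions and the macrophage list over the alternatives, 913 were as reported, 91 lost their call and 1 gained one. The 913 include regions that were called in neither fit, so they do not measure how stable the 12 calls were.

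Replicate numbers did not pair the libraries: same-numbered libraries correlated at −0.13, −0.01, −0.07 and −0.07 in their deviations from group means, and 0 of 4 correlated best with its own number. With the replicate block, edgeR called 1 region (1 higher, 0 lower; 3033 at an unadjusted p under 0.05), 1 within 150 kb of Itgax, 1 of the 12 named and 0 gene lists (macrophage list adjusted p = 0.0531); the Opa1 region was at −0.10 and the gene-end difference at −0.556 (exact permutation p = 0.5). Motif tests and the GC correction, with and without the block, were not run, since they need a genome sequence. In simulated data with these library sizes, this spread, independent regions and 4 libraries per group, 23.9% of 1.5-fold changes were called. Depth was not varied, so its share in this limit was not tested.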

Other observations

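The stretches below were sought after the results were seen, and the test of other splits for them was written before its result.

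Stretches of consecutive regions with one sign were found elsewhere, named here after their values were seen. Of the 19 with the largest summed z apart from that at Itgax, 15 were lower and 4 higher in OPA1-deficient libraries. At the inflammatory chemokine cluster on chromosome 11, from 83550118 to 83649985, which holds Ccl5, Ccl9, Ccl6, Ccl3 and Ccl4, 18 consecutive regions had positive log2 fold changes (median 0.35, from 0.01 to 0.85). At Plcb1, a phospholipase C gene, and its neighbour Plcb4 on chromosome 2, from 135361934 to 135725850, 12 were positive (median 0.52, from 0.10 to 1.47). From Basp1 to Myo10, an unconventional myosin gene of filopodia, on chromosome 15 from 25413328 to 25830890, 19 were negative (median −0.35, from −1.59 to −0.01). On chromosome 3, 17 regions spread from 10315516 to 14871673 were negative (median −0.32, from −1.73 to −0.02), among them regions nearest the carbonic anhydrase genes Car1, Car3 and Car13. None of the 12 called regions lay in these stretches.

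A hypothesis that such stretches mark domains altered with genotype was set against other splits of the libraries. Chance could not be excluded: 9 of 35 splits held a stretch over 500 kb from Itgax with as large a summed z, with a size of 32.9 in the real split and 71.7 in the highest other.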
